A study of Homo sapiens with 4 samples.

How the data were processed

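The data were 4 poly(A) RNA-seq libraries, read paired-end on an Illumina instrument, from U87MG and U251 glioblastoma cells with a control hairpin or a hairpin against SRSF1. Groups were taken from the sample titles, and the treatment text assigns the control hairpin to the libraries titled WT. The deposited table holds RPKM values per gene, already scaled by the authors to gene length and library size, with a gene type, a KEGG identifier and a description per row. Per the submitters' processing notes, reads were aligned with Bowtie 0.12.2 to hg19. The counting program, gene annotation, strand setting and treatment of reads that fit several places are not given in the sources used here, so overlapping and antisense genes cannot be told apart either. All 4 columns of values were used. The design had foreseen a count test only if the table held counts. Because the unit is RPKM, limma on log values was the main test.

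RPKM values of low genes in a library are whole multiples of the value of 1 read, which gave the relative depth of the libraries from 3032 low genes. Small RNA genes of known length then gave the reads per library, with 336 of 380 genes giving the same total. With these totals, 27928 of 27973 genes above 0 (99.8%) came out as whole reads in every library within 0.01 reads, for the shortest gene model up to 40000 bases that allowed it. After multiplying 500 genes by random factors 2.6% passed. The recovered reads are the smallest whole numbers that fit, and made up 96.3% to 97.4% of each library total. An RPKM of 1 in a gene of 1 kilobase rests on about 26 reads, since 1 read was worth 0.0358 to 0.0398 RPKM there. Counting intervals are 95% exact Clopper-Pearson intervals of the knockdown share of a gene's recovered reads, scaled by depth, and cover counting error only.

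Ratios used log2 of RPKM + 1, and genes needed an RPKM of at least 1 in at least 1 library. Within a line only values and counts at 2-fold are given. Across lines, limma 3.58.1 in R 4.3.3 was fitted with the cell line as a block and an intensity trend in eBayes, two-sided, with Benjamini-Hochberg adjustment over 16098 genes. This leaves 1 residual degree of freedom per gene, so the test leans on the variance shared across genes. The sources do not say whether the libraries of a line came from separate infections, so p-values measure only the spread between these libraries. The coefficient for the cell line came from the same fit. The overlap of the lines was set against 1000 shuffles of the U251 ratios within bins of 100 genes by mean expression.

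A total of 45 gene lists were fixed before the data were examined, of which 40 had at least 5 measured members. The median ratio of a list in each line was placed among 10000 random lists, in which each member was replaced by a gene among its 200 nearest by mean log2 expression. A list stood apart below the 2.5th or above the 97.5th percentile, and in both lines only on the same side. Members were matched by symbol, or by Entrez identifier where symbols had changed. The named genes followed a rule fixed before the data were examined, except within the gene lists. There the plan was to rank members by the mean of the absolute ratios of the lines. Instead the absolute value of their mean ratio was used, which favours genes that moved the same way in both lines. SRSF1 came first, then genes with an RPKM of at least 5 in each line and a protein-coding-style symbol, ranked by the smaller absolute ratio of the 2 lines. These were the 12 highest and 12 lowest, 5 of each kind with opposite directions, the 5 highest and 5 lowest per line with an absolute log2 ratio under 0.5 in the other line, up to 4 per list, all SR proteins, and 8 in each direction between the lines.

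Transcript sequences of GENCODE 29 on GRCh38 served for 2 searches added after the data were examined. The 3' UTRs of 11120 genes were searched for every heptamer, with the ratio adjusted for 3' UTR length and GC content, and heptamers present in at least 50 genes were ranked. The search was repeated in 100 random sets of 50% of these genes, and carriers were compared in the genes held out, also with the 50 nearest genes there by 3' UTR length, GC content and expression. A gene counted as having a near-identical copy when at least 50% of its 31-base words occurred in another annotated gene. The pairs of copies named were chosen after their values were seen. Positions are those of GRCh38, and none were converted from hg19. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

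The steps were tested on simulated data before use. Reads were drawn for 16097 genes at the real means and depths, with a spread of 0.15 log2 units per library and 200 genes changed in both lines. For the comparison across lines, limma called 55 of 100 genes changed by 2-fold and 81 of 100 changed by 4-fold in the right direction. It also called 22 unchanged genes among 158 calls, more than the 5% aimed at. None of these 22 was of type mRNA (100 calls), and of the 606 real calls 100 were of other types. The simulation gave every gene the same independent spread, and changed genes the same change in both lines. It therefore does not give the share of false calls among the real ones. Fitted ratios were smaller than the simulated ones (medians 0.79 for 1 and 1.57 for 2) because of the pseudocount. Of 200 unchanged gene lists 9 stood apart in U87MG and 7 in U251. A planted heptamer ranked 1 of those searched in 3000 simulated genes.

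Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter, an RPKM minimum of 5, trimmed-mean rescaling, quantile normalization, no block, eBayes without trend or with robust estimation, fold thresholds of 1.5 and 3, list members at an RPKM of at least 5, and the 500 nearest genes. Chosen after seeing the data were mRNA rows only, totals without mitochondrial reads, voom on recovered reads, choosing the heptamer in a random set of the genes, and leaving out genes with the heptamer or with near-identical copies.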

Results

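Poly(A) RNA was sequenced from 4 libraries of 2 human glioblastoma cell lines, U87MG and U251, each carrying either a control short hairpin or a hairpin against SRSF1. SRSF1 encodes a serine/arginine-rich (SR) protein that binds exonic sequences and acts in constitutive and alternative splicing. The hairpins were delivered by lentivirus at a multiplicity of infection of 20, followed by 1 week of puromycin selection. There was 1 library per cell line and arm, so the knockdown was replicated only across the 2 lines, and a difference within a line has no replicate check. The values were RPKM (reads scaled to gene model length and library size). The reads behind them came to 26298575 in the U87MG control, 25974900 in the U87MG knockdown, 25099799 in the U251 control and 27953878 in the U251 knockdown. Of the 40205 rows, 16098 reached an RPKM of 1 in at least 1 library and entered the comparisons, 11816 of them mRNA genes. Ratios below are log2 of (knockdown RPKM + 1) over (control RPKM + 1), which understates the change of weakly expressed genes.

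The first question was whether the targeted gene was lower in the libraries labelled as knockdown. SRSF1 stood at 88.3 RPKM in the U87MG control and 14.6 RPKM in the U87MG knockdown, and at 109 and 15.8 RPKM in the U251 control and knockdown. By recovered reads the knockdown level was 0.166 times the control level in U87MG (95% Clopper-Pearson interval 0.158 to 0.173) and 0.145 times in U251 (0.139 to 0.151). These intervals cover counting error only. The log2 ratios of SRSF1 were -2.52 and -2.71, and across the lines limma gave -2.62 ± 0.16 (SE, n = 2 libraries per arm, adjusted p = 0.0022). SRSF1 lies on chromosome 17 from 58003360 to 58007346, reverse strand, in GRCh38. Of the 31-base words of its longest transcript, a share of 0.59 also occurs in another annotated gene, so some of its reads could have been assigned elsewhere.

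The other SR protein genes differed far less between the arms than SRSF1. Among the 12 measured, 11 were lower in the U87MG knockdown and 7 in the U251 knockdown, and the list medians were -0.27 and -0.30. The U251 median lay at percentile 0.1 of random lists matched on expression and the U87MG median at percentile 2.9, just inside the range. SRSF2 fell (log2 ratio -0.80 ± 0.16, adjusted p = 0.041 by limma). Adjusted over the list alone, 4 SR genes were called lower. SRSF7 had ratios of -0.93 in U87MG and -0.39 in U251, SRSF3 -0.74 and -0.46, and TRA2B -0.60 and -0.52. SRSF4, SRSF5, SRSF6, SRSF9 and SRSF11 had limma estimates between -0.02 and 0.13, with SEs of 0.15 to 0.16.

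**Figure D1:**
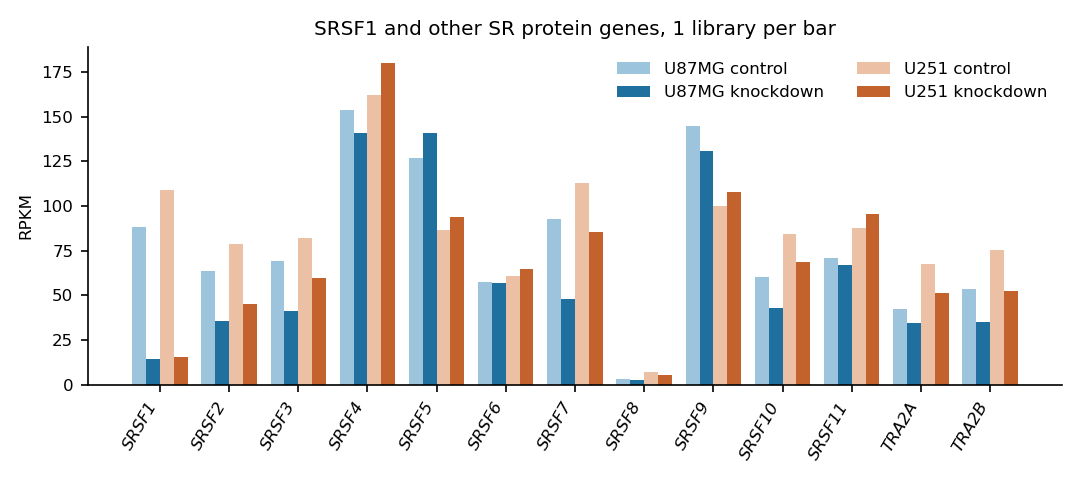
RPKM of SRSF1 and 12 other SR protein genes, with 1 bar per library and therefore no error bars. SRSF1 stands at 14.6 and 15.8 RPKM in the knockdown libraries against 88.3 and 109 in the controls, and no other gene shown differs by as much.

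Genes for hnRNP proteins, RNA-binding proteins that often act against SR proteins in exon choice, were lower as a group in both lines. Of 27 measured, 25 were lower in U87MG and 22 in U251, with medians of -0.33 and -0.22, each below the matched random lists (percentile 0.0). HNRNPH1 fell from 297 to 125 RPKM in U87MG and from 512 to 310 RPKM in U251 (-0.98 ± 0.17, adjusted p = 0.029 by limma). It was the only hnRNP gene called over all genes, and 7 were called lower and 1 higher when adjusted over the list alone. PTBP1 had ratios of -0.73 and -0.64, HNRNPH3 -0.69 and -0.62, and HNRNPA1 -0.64 and -0.54. Core spliceosome genes had a median of -0.22 in U87MG (percentile 1.1) and 0.02 in U251 (percentile 15.1), with none of 38 called over all genes or adjusted over the list alone. Nonsense-mediated decay factors and SR protein kinases had medians within the range of random lists in both lines.

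The second question was what each line showed at a fixed fold. In U87MG 375 genes were at least 2-fold higher and 577 at least 2-fold lower in the knockdown library. In U251 188 were higher and 275 lower. The excess of lower genes in U87MG depends on the scaling, with 478 higher and 463 lower after trimmed-mean rescaling and 420 and 461 after quantile normalization. The 2 lines share no library, and across genes their ratios correlated with Pearson r = 0.48 and Spearman rho = 0.49. Genes are not independent replicates, so no p-value is given. At 2-fold, 63 genes were higher in both lines and 95 lower in both, against means of 7.17 and 12.2 when the U251 ratios were shuffled among genes of like expression, and at most 17 and 26 in 1000 shuffles. Only 8 genes passed 2-fold in opposite directions, against a shuffled mean of 17.4.

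**Figure D2:**
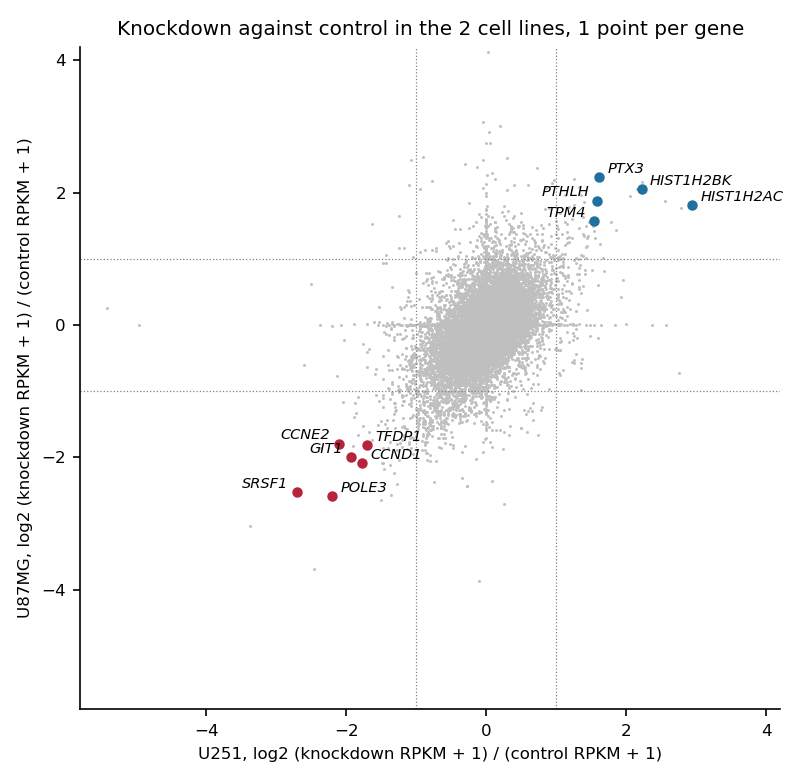
Log2 ratio of knockdown over control in U251 (horizontal) and U87MG (vertical), 1 point per gene, with dotted lines at 2-fold. SRSF1, at -2.71 and -2.52, lies at the lower left with POLE3 and CCND1, and HIST1H2AC, at 2.94 and 1.81, lies at the upper right.

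Taking the cell line as a block, limma called 186 genes higher and 420 lower in the knockdown libraries (2 libraries per arm, Benjamini-Hochberg adjusted p under 0.05). Next to SRSF1, the genes with the most negative ratios in both lines included several of DNA replication and the cell cycle. POLE3, a histone-fold subunit of DNA polymerase epsilon, fell from 58.9 to 9.02 RPKM in U87MG and from 62.4 to 12.8 RPKM in U251 (-2.39 ± 0.18). CCND1, encoding cyclin D1, fell from 238 to 55.1 and from 127 to 36.4 RPKM (-1.94 ± 0.16). CCNE2, encoding cyclin E2, fell by 1.95 on the log2 scale, TFDP1, the dimer partner of E2F factors, by 1.75, and POLA1, the catalytic subunit of DNA polymerase alpha, by 1.81. GIT1 (-1.97), FTSJ3 (-1.68), C1GALT1C1 (-1.64), CTDSPL2 (-1.53) and FAM111B (-1.78) fell as well. Of the 12 lowest genes, 11 had a searchable 3' UTR, and in 5 of these (POLE3, CCND1, GIT1, FTSJ3 and C1GALT1C1) the 3' UTR contains GACGTGT, the heptamer whose carriers shifted downward most in both lines. None of the 10 searchable 3' UTRs among the 12 highest genes contains it. The heptamer was chosen on these same ratios, so its presence among the lowest genes is partly built in. Only 2.78% of all searched genes carry it, so its absence from these 10 carries no weight. VAMP7 and WASH4P also rank among the lowest, but shares of 1 and 0.88 of their 31-base words occur in another annotated gene, so their values are uncertain.

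The genes with the highest ratios in both lines included histone genes and secreted factors. PTX3, encoding the secreted pattern-recognition protein pentraxin 3, rose from 28.4 to 138 RPKM in U87MG and from 4.44 to 15.7 RPKM in U251 (1.93 ± 0.20). PTHLH, encoding parathyroid hormone-related protein, rose by 1.74 on the log2 scale. TPM4, a tropomyosin of the actin cytoskeleton, rose from 279 to 832 and from 205 to 600 RPKM (1.56 ± 0.14). NUPR1, a stress-induced chromatin protein, rose by 1.51, BEX2 by 1.63 and IL31RA, a cytokine receptor subunit, by 1.40. RPL32P29, a pseudogene whose words all occur in other genes, and RPS29, from 3.42 to 11.9 RPKM in U87MG, also rank among the 12 highest, as do 3 histone genes. After trimmed-mean rescaling 6 genes were called higher and 5 lower, so the share of higher calls moved from 30.7% to 54.5%. All 606 calls kept their direction with an unadjusted p under 0.05 by limma. That is no check, since they were chosen for low p-values in the same libraries. The prior degrees of freedom, the weight eBayes puts on the shared variance, fell from 6.74 to 4.26. The adjusted p-values given here therefore depend on the scaling. After quantile normalization 334 were called higher and 532 lower, with 183 of the 186 higher and 418 of the 420 lower calls among them, and without the block for cell line none was called (79 higher and 183 lower at an unadjusted p under 0.05).

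Cell-cycle genes were lower as a group in both lines. All 33 measured G2/M genes were lower in both lines, with medians of -1.47 in U87MG and -0.78 in U251. At least 2-fold lower were 30 of them in U87MG and 2 in U251. Over all genes 22 were called lower by limma, and adjusted over the list alone all 33 were. MKI67, the proliferation antigen, fell from 91.1 to 20.2 RPKM in U87MG and from 124 to 47.6 RPKM in U251 (-1.74 ± 0.21), PRC1, a midzone microtubule bundler, by 1.64, CDC20, an activator of the anaphase-promoting complex, by 1.38, and PLK1, a mitotic kinase, by 1.37. Of 30 G1/S genes 29 were lower in each line, with medians of -1.27 and -0.38. Over all genes 12 were called lower, and 25 when adjusted over the list alone. RRM2, a subunit of ribonucleotide reductase, fell from 113 to 18.2 RPKM in U87MG and from 171 to 66.2 RPKM in U251, and CLSPN, a replication checkpoint mediator, from 18 to 3.93 and from 22.5 to 10.3 RPKM. Both lists lay below all matched random lists in both lines (percentile 0.0). No member of either list carries the heptamer GACGTGT in its 3' UTR, and 1 G1/S gene carries it outside the 3' UTR. The larger medians in U87MG than in U251 were not tested as a difference.

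Homologous recombination and repair genes went the same way, with 21 of 22 lower in U87MG (median -0.97) and 20 in U251 (median -0.40). By limma 6 were called lower over all genes and 13 adjusted over the list alone. BRCA1 fell from 18.5 to 4.83 RPKM in U87MG and from 29 to 14 RPKM in U251 (-1.37 ± 0.21, adjusted p = 0.021), FANCI by 1.34 and FANCD2 by 0.95. Among the 4 measured cyclin-dependent kinase inhibitors, CDKN3 fell (-0.97 ± 0.18). CDKN1A, encoding p21, was at 49.9 and 53.7 RPKM in the U87MG control and knockdown, and at 9.08 and 3.45 RPKM in U251. The p53 target list had a median of -0.01 in both lines. Within it DDB2, a damage-recognition protein, fell by 1.63 and GDF15, a stress-induced cytokine, rose by 1.09.

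Interferon-stimulated genes were lower as a group in both lines, with medians of -0.38 in U87MG and -0.48 in U251 (percentile 0.0 in each). Of 35 measured, 27 and 29 were lower, 7 were called lower over all genes and 11 adjusted over the list alone. OAS3, an RNA-sensing synthetase, fell by 1.22, IFITM3, a membrane restriction factor, by 1.16 and USP18, an ISG15 protease, by 1.02. Genes of the integrated stress response were higher as a group, with medians of 0.29 and 0.35 (percentile 100.0 in each line). Of 27, 20 were higher in U87MG and 22 in U251, and 4 rose over all genes, against 12 called higher and 1 lower adjusted over the list alone. Besides NUPR1, ATF3 rose by 1.29, DDIT3, encoding CHOP, by 1.16 and TRIB3 by 1.08. HSPA5, the endoplasmic reticulum chaperone BiP, rose from 1500 to 2650 RPKM in U87MG and from 306 to 553 RPKM in U251 (0.84 ± 0.13). The median of the ER chaperone list was 0.47 in U87MG (percentile 100.0) and 0.16 in U251 (percentile 83.6).

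Replication-dependent histone genes, most of whose mRNAs lack a poly(A) tail, were higher in these poly(A) libraries. Of 18 measured, 14 were higher in U87MG (median 0.54) and 17 in U251 (median 1.08), each above the matched random lists. By limma 9 rose over all genes and 10 adjusted over the list alone. HIST1H2AC went from 6.74 to 26.1 RPKM in U87MG and from 9.69 to 81.2 RPKM in U251 (2.37 ± 0.26), HIST1H2BD rose by 2.22, HIST1H2BK by 2.14 and HIST1H2BJ by 1.64. Members of this family are similar in sequence, and for HIST1H2BK a share of 0.86 of its 31-base words occurs in another gene.

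**Figure D3:**
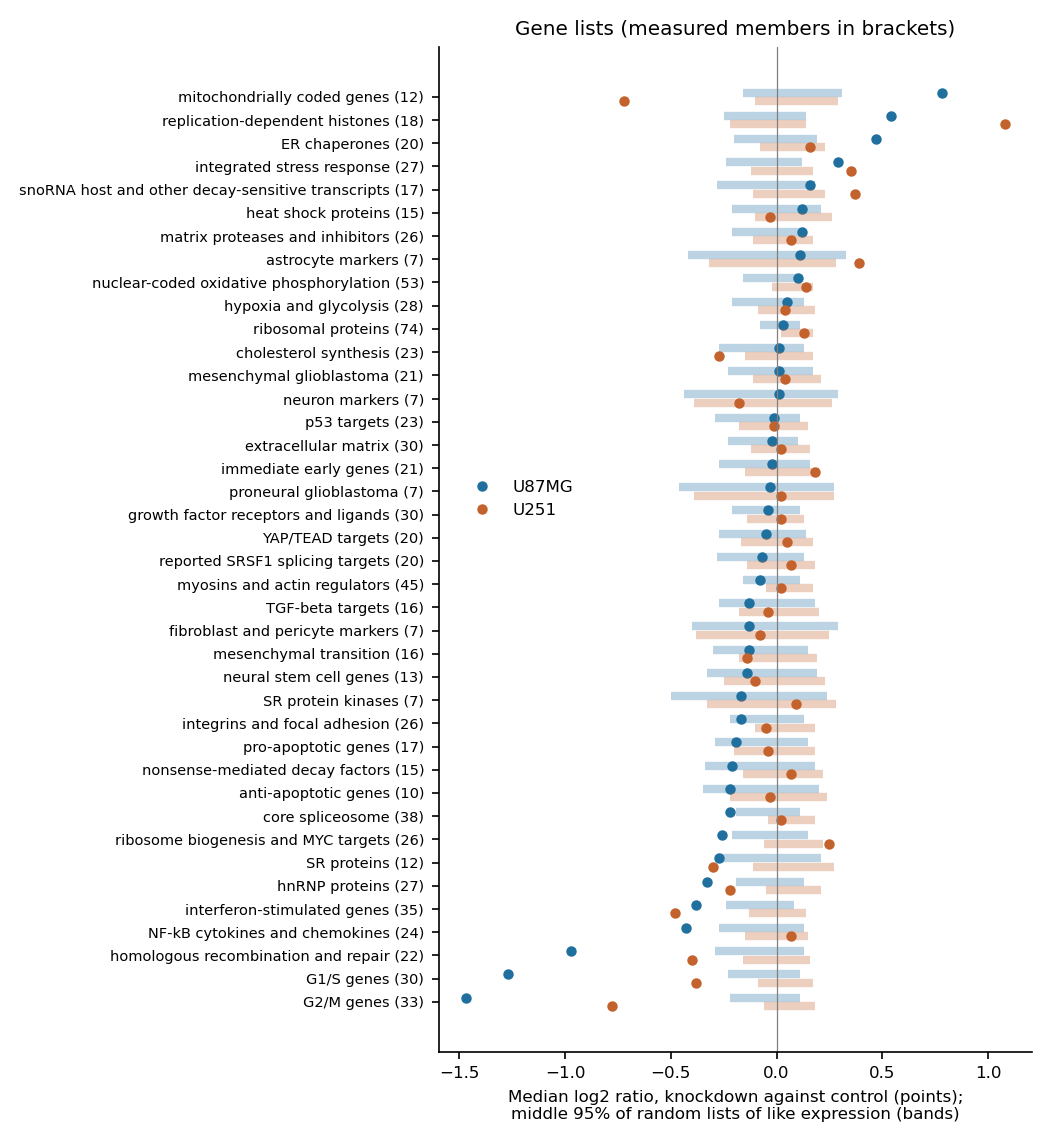
Median log2 ratio of knockdown over control for 40 gene lists in U87MG (blue) and U251 (orange), with bands for the middle 95% of 10000 random lists of like expression and the number of measured members in brackets. G2/M genes lie lowest in both lines (-1.47 and -0.78), and mitochondrially coded genes lie at 0.78 in U87MG and -0.72 in U251.

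**Figure D4:**
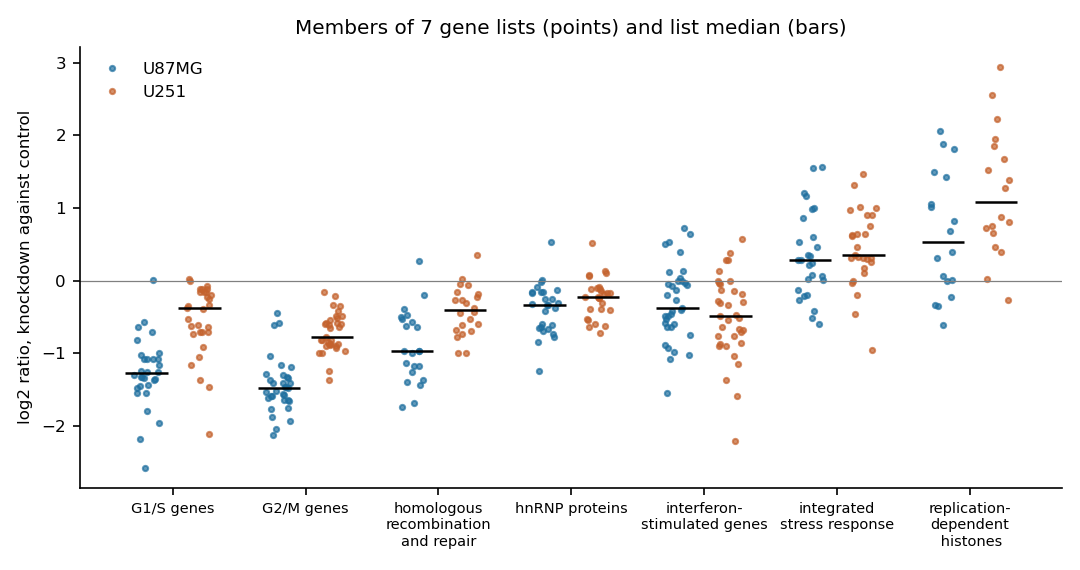
Log2 ratio of knockdown over control for each measured member of the 7 lists that stood apart on the same side in both lines, with black bars at the list medians. All 33 G2/M genes lie below 0 in both lines, and the histone medians lie at 0.54 and 1.08.

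The list of 20 genes reported as SRSF1 splicing targets had medians of -0.07 and 0.07, within the range of random lists. Gene-level values do not show isoforms, so splicing itself was not analysed here. In this list CCND1 and MCL1, an anti-apoptotic BCL2 relative (-0.79 ± 0.16), fell over all genes. Adjusted over the list alone, 3 members were called higher and 4 lower. BCL2L1 had ratios of 0.50 and 0.92, and RAC1 0.61 and 0.79. Among actin regulators CTTN, encoding cortactin, rose by 0.91 and LIMK1 by 0.79. In the matrix, adhesion and mesenchymal transition lists FBN1, encoding fibrillin 1, fell by 1.48, VCAN, encoding versican, by 1.22, AXL, a receptor tyrosine kinase, by 1.02 and ITGA2 by 0.88, while SPP1, encoding osteopontin, rose by 1.38, ITGB3 by 1.01 and SERPINE2 by 1.07. The medians of these lists lay within the range of random lists in both lines.

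Some genes moved far more in 1 line than in the other, where their absolute log2 ratio was under 0.5 but not always near no change. These differences between lines were not tested, since the interaction has no residual degree of freedom. ANKRD1 was at 0.674 and 12.5 RPKM in the U87MG control and knockdown and at 31.5 and 36.3 RPKM in U251. SOD2, the mitochondrial superoxide dismutase, was at 140 and 434 RPKM in U87MG and at 32.3 and 34.1 RPKM in U251. FBXO32, a muscle-atrophy ubiquitin ligase, and BAMBI, a TGF-beta pseudoreceptor, had ratios of 1.63 and 1.59 in U87MG and -0.07 and -0.47 in U251. Lower in U87MG, with ratios closer to 0 in U251, were ORC1 (-1.81 and -0.48), MCM4 (-1.48 and -0.39), MAD2L1 (-1.47 and -0.35) and RFC5 (-1.45 and -0.29), all of replication or the spindle checkpoint. NF-kB cytokines and chemokines had a median of -0.43 in U87MG (percentile 0.0) and 0.07 in U251 (percentile 79.1). CXCL3 was at 165 and 24.4 RPKM and IL1B at 665 and 194 RPKM in U87MG, while both were under 2.5 RPKM in U251. In U251, PREX1, NOLC1, IGFBP6 and SDC4 had ratios between 1.28 and 1.32, and MME, NEAT1, EGR1 and CDKN1A ratios between -1.54 and -1.18. Among these genes, the furthest from no change in U87MG were NEAT1 (-0.47, also lower) and IGFBP6 (-0.44, the opposite direction). CD99 was at 43.1 RPKM in the U251 control and 0.0279 RPKM in the U251 knockdown (1 read, read ratio 0.000647, 95% Clopper-Pearson interval 1.64e-05 to 0.00361), and GTF2H2 at 44.8 and 7.48 RPKM in U87MG, but shares of 1 and 0.79 of their words occur in another annotated gene, so both values are uncertain. The same limit applies to SOD2, with a share of 0.66, and to PRC1 (0.65) and ITGB3 (0.56) named above.

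The last comparison was between the lines. By limma 3482 genes were higher and 4347 lower in U87MG than in U251 (2 libraries per line, the arm as a covariate), and 1144 were at least 2-fold higher and 1528 at least 2-fold lower in both arms. LDHA, encoding lactate dehydrogenase A, was at 424 and 327 RPKM in the U87MG libraries (control and knockdown) and at 11.1 and 7.14 RPKM in U251. IL8, a neutrophil chemokine, was at 789 and 748 RPKM in U87MG against 23.7 and 34.7 RPKM in U251. HMOX1, the inducible heme oxygenase, was higher in U87MG by 4.34 ± 0.17 on the log2 scale, ADAMTS1 by 4.35, BASP1 by 4.27, TNNT1 by 3.85 and NAMPT by 3.82. NAMPTL, a NAMPT-like copy, was higher by 3.76. IFI6, an interferon-induced gene, was at 864 and 1060 RPKM in U251 against 8.93 and 6.09 RPKM in U87MG. IGFBP7 (-5.65 ± 0.17 for U87MG minus U251), CTGF (-4.55), H1F0 (-4.31), SLC9A3R2 (-4.06), COL6A1 (-3.33), CYR61 (-3.35) and DKK1 (-3.15) were also higher in U251. Adjusted p-values by limma for these 16 genes ranged from 7.5e-07 to 2.9e-05.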

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

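The tests of near-identical copies and of a common factor on mitochondrial transcripts were chosen after the results were seen. The genes and lists below stood out because the knockdown library lay on 1 side of its control in U87MG and on the other side in U251. With 1 library per line and arm, none of these differences between the lines was tested. Ribosome biogenesis and MYC target genes had medians of -0.26 in U87MG and 0.25 in U251, a median difference of -0.55 (U87MG minus U251). The ratio of CPA4, a secreted carboxypeptidase, differed by 2.95 (0.985 to 8.01 RPKM in U87MG, 123 to 71.8 RPKM in U251). IL11, a cytokine, differed by -1.79 (10.8 to 7.16 and 22.7 to 55.8 RPKM), C11orf83 by -1.63 (12.1 to 6.02 and 6.05 to 10.7 RPKM) and ST3GAL1, a sialyltransferase, by -1.35 (57 to 38.8 and 3.38 to 6.66 RPKM). MIR100HG, a microRNA host transcript, differed by -1.13, and MAP2K3, a kinase upstream of p38, by -1.09.

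Transcripts of the mitochondrial genome were higher in the U87MG knockdown (list median 0.78) and lower in the U251 knockdown (-0.72), a median difference of 1.41, with ND2 at 1.60, ND4 at 1.65 and ND3 at 1.91. Mitochondrial genes held 2.56% and 4.65% of recovered reads in the U87MG control and knockdown, and 5.35% and 3.97% in U251. A single factor on all mitochondrial RNA would move the rRNAs with the mRNAs, and in U87MG RNR1 (0.94) and RNR2 (1.04) lay 0.21 from the mRNA median. The 12 mRNAs themselves ranged from 0.13 (ND6) to 1.13 (ND3) in U87MG, so they did not all move alike. With 1 library per arm that spread was not tested. A single factor therefore stays open in U87MG, though perhaps only as part of the cause. In U251 RNR1 (0.29) and RNR2 (0.14) were higher while 11 of 12 mRNAs were lower (ND6 was at 0.02), a gap of 0.93 to the mRNA median, which argues against it as the whole cause in that line. Nor did mitochondrial reads crowd out other genes, since leaving them out of the totals moved the median ratio of nuclear-coded mRNAs by at most 0.028, while a response that differs between the lines and a difference in the handling of single libraries remain open and untested.

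NOMO3 also went opposite ways, with ratios of 1.16 in U87MG and -1.24 in U251, a difference of 2.40, and a share of 0.96 of its 31-base words occurs in another annotated gene. Reads that fit several copies may have been assigned to different copies in different libraries. Genes with such a copy passed 2-fold in 8.03% of cases in U87MG against 5.25% of expression-matched genes (6.67% at the upper end of the middle 95% of draws), and in 4.38% against 2.83% in U251 (3.86%), so the smaller excess was 1.55 percentage points. The sum over SERF1A and SERF1B had ratios of 0.15 and 0.50 where SERF1A alone had -2.43 and -0.27, SMN1 plus SMN2 had 0.05 and 0.12 where SMN1 had 0.52 and -0.51, EIF3C plus EIF3CL had -0.24 and 0.05 where EIF3C had -0.43 and -0.08, while SLX1A plus SLX1B still had -1.25 and -0.52. How reads that fit several places were counted is not given in the sources used here, and no biological explanation was tested.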

How the results depend on the processing

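The settings restricted to mRNA genes, to totals without mitochondrial reads, to voom, and to genes without the heptamer or without copies, and the choice of the heptamer in a random set of genes, were chosen after seeing the data. The planned edgeR alternative was not run, because the values are RPKM. Leaving out 1 library leaves 0 residual degrees of freedom, so the ratios of the single lines stand as the values without it. The 7 lists that stood apart on the same side in both lines kept that side under all 12 alternatives run for lists. Of 1215 recomputed values of genes and lists at 2-fold or more all 1215 kept their sign, which is no check of robustness. A pseudocount or a filter cannot reverse the ratio of a gene, and rescaling was small against 2-fold (trimmed-mean factors of 0.9498 to 1.024). The counts depended on the settings, and where no reason is given the cause was not tested. With a pseudocount of 0.1, which enlarges ratios of low genes by construction, 726 genes were higher and 1101 lower in U87MG, 470 and 719 in U251, 160 and 282 in both, 65 opposite, r = 0.39, and SRSF1 stood at -2.59 and -2.78. With 0.5, 437 were lower in U251, 159 lower in both and 24 opposite. With an RPKM minimum of 5, 182 were lower in U251, 4 opposite, r = 0.56, and limma called 301 higher. Among mRNA genes 239 were higher in U87MG, 117 higher and 181 lower in U251, 1 opposite, r = 0.56, and limma called 364 higher and 772 lower. At 1.5-fold, by construction, 1236 were higher and 1848 lower in U87MG, 807 and 1245 in U251, 280 and 606 in both and 63 opposite, and at 3-fold 72 and 102, 25 and 37, 9 and 13, and 0. SRSF1 in U87MG stood at -2.41 after trimmed-mean rescaling and -2.42 after quantile normalization, which gave -2.82 in U251. By limma, 6 genes were called higher and 5 lower after trimmed-mean rescaling, where all 606 calls had an unadjusted p under 0.05 in the same direction. Since these calls were chosen in the same libraries, that too is no check of robustness. The prior degrees of freedom were 4.26 after this rescaling and 2.24 without a filter, against 6.74 in the main fit. Quantile normalization gave 334 higher. Totals without mitochondrial reads gave 272 lower, and eBayes without trend 88 higher and 172 lower. Leaving out genes with the heptamer anywhere in the mRNA (7.98% of searched mRNAs) left 66 genes lower and 61 higher in both lines. With main counts of 95 and 63, the loss lay mostly among lower genes. There limma gave 289 lower and 150 higher. The heptamer was chosen on these ratios, so part of this loss was built in. Voom gave 610 higher and 1111 lower, with 172 of the 186 higher and 405 of the 420 lower calls shared. Without a filter limma called 0 higher and 0 lower (1234 and 1890 at an unadjusted p under 0.05), and 1856 higher and 2430 lower in U87MG than in U251. Without the block it called 0 and 0 (79 and 183). Depth limits low genes, since 1 read in a gene of 1 kilobase is 0.0358 to 0.0398 RPKM.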

Other observations

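The heptamer search, the test of 3' UTR length and GC content and the comparisons in held-out genes were chosen after the results were seen. Several other lists held genes that moved in both lines. UPP1, encoding uridine phosphorylase 1 and listed with decay-sensitive transcripts, rose from 64.4 to 230 RPKM in U87MG and from 20.1 to 49.4 RPKM in U251 (1.54 ± 0.19, adjusted p = 0.013 by limma). The median of that list was 0.16 in U87MG, within the range of random lists, and 0.37 in U251, above it, and adjusted over the list alone 4 members were called higher and 2 lower. SLC2A3, a glucose transporter of the hypoxia and glycolysis list, rose by 1.55. Among mesenchymal glioblastoma genes CEBPD, a transcription factor, rose by 1.48, LGALS3, encoding galectin 3, by 1.07 and ANXA1, encoding annexin A1, by 0.75. Among YAP/TEAD targets CYR61, a matricellular protein, rose by 1.11 and TEAD4 fell by 0.94, and among immediate early genes DUSP5, a phosphatase, rose by 0.98 and JUNB fell by 1.04. The medians of these 4 lists lay within the range of random lists in both lines. Both genes named here as falling, TEAD4 and JUNB, carry the heptamer GACGTGT in the 3' UTR, but that heptamer was chosen on these same ratios. Cholesterol synthesis genes had a median of 0.01 in U87MG and -0.27 in U251 (percentile 0.1), and astrocyte markers 0.11 and 0.39 (percentile 99.4 in U251), with none of either called over all genes.

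Of 16190 heptamers searched in the 3' UTRs of 11120 genes, GACGTGT had the most negative score in each line (z = -9.70 in U87MG and -13.05 in U251). The score for both lines was -16.09, against a largest absolute score of 6.14 in 200 permutations of genes. The 309 genes carrying it had a mean ratio of -0.35 in each line. The 293 with 1 site had means of -0.34 ± 0.030 (SE over genes) in U87MG and -0.33 ± 0.030 in U251. For the 16 with at least 2 sites the means were -0.45 ± 0.115 and -0.67 ± 0.162. In U87MG the means for 1 site and for more differed by less than the larger SE. A dependence on the number of sites was not tested. Carriers made up 2.78% of searched genes, 22 of the 74 at least 2-fold lower in both lines (29.7%), 49 of 343 called lower by limma (14.3%) and 0 of 143 called higher. No p-value is given for these shares, because the heptamer was chosen on the same ratios. When it was chosen in a random set of 50% of the genes, GACGTGT came first in 100 of 100 draws, and in the held-out genes it was carried by 29.2% of those at least 2-fold lower in both lines (15.6% to 39.5% over draws) against 2.76% of all. In GRCh38 the site of POLE3 lies on chromosome 9 from 113407336 to 113407342 (context GACAGGTAGTGACGTGTAGTTTGACAC). That of CCND1 lies on chromosome 11 from 69653138 to 69653144 (TGTGGAGGCTGACGTGTGAGGGAGGAC). That of FTSJ3 lies on chromosome 17 from 63819492 to 63819498 (TCTACACCTGGACGTGTGGGCCACTTA). SRSF1 carries the heptamer once, in the coding part of exon 1 (chromosome 17, 58007032 to 58007038, context GGACATTGAGGACGTGTTCTACAAATA), and 4.8% of coding sequences contain it. In the SRSF1 transcript with the longest 3' UTR, which was the one searched, it starts at base 100 of a coding sequence of 606 bases. Other SRSF1 transcripts may differ in coding length.

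A candidate explanation is that the hairpin against SRSF1 acted on other mRNAs through a seed match, so that the lower POLE3 and CCND1 may not follow from the loss of SRSF1. Carriers in the 3' UTR had a lower mean than carriers in the coding sequence or 5' UTR alone, by -0.14 ± 0.037 (SE over genes) in U87MG and -0.17 ± 0.034 in U251, which goes with this hypothesis (medians of -0.13 and -0.17 in held-out genes, negative in both lines in 100 of 100 draws), while 3' UTR length and GC content are argued against, since carriers lay -0.29 and -0.32 from matched genes, also as medians in held-out genes (at most -0.20 and -0.24 in any draw). A loss of SRSF1 acting through the heptamer anywhere in the mRNA cannot be told apart, because the 578 coding or 5' UTR carriers also lay -0.15 from matched genes in both lines, and the hairpin sequence is not given in the sources used here. For the cell-cycle genes, a match to GACGTGT in their own 3' UTRs is argued against, since none of them carries it there. The G1/S median in U87MG was -1.26 without the 1 gene that carries it elsewhere in the mRNA. Other forms of a seed match stay open for these genes. Heptamers such as ACGTGTA (score for both lines -10.32) and TGACGTG (-8.12) also passed the permutation maximum of 6.14, and they were not counted in these genes. Effects passed on from CCND1, POLE3 or other carriers stay open as well. The heptamer with the highest score, TCGGAGA, reached z = 5.38, below the permutation maximum of 6.14. Its 3' UTR carriers lay 0.10 ± 0.036 (SE over genes) above other carriers in U87MG and 0.05 ± 0.029 in U251. They also lay 0.11 and 0.12 above matched genes, but the heptamer was chosen on these ratios. An action of the control hairpin therefore cannot be told apart from none.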
